A study of Mus musculus with 48 samples.

How the data were processed

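ATAC-seq libraries of 24 mouse ER-Hoxb8 clones were analysed, 1 of progenitors and 1 of monocytic cells per clone. The labels name a clone number and a state for each library, and the pairing of both states by clone comes from the series design text. Each library was given as a deposited list of peaks in 10 columns without a header. Per the submitters' processing notes, reads were aligned with Bowtie2 to mm10. The peak caller, its threshold and the handling of duplicates are not given in the sources used here.

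The units were read from the values. The deposited fold column is a ratio of the peak's pileup over the local background of the same library. The deposited signal column is the pileup (coverage) at the peak's highest point, not scaled to depth. The last deposited column behaves as a -log10 of a q value, since it lay below the -log10 of the Poisson tail of the pileup given the implied background. Across peaks of a library, which are not independent replicates, both were correlated at r = 0.983 or more on a log scale in all libraries but the progenitors of clone 18 (0.238), whose kept peaks had a median pileup of 1. That library stayed among those compared. Read depth per library is unknown, so no interval that needs it is given. As a stand-in for depth, the lowest background pileup implied by (pileup + 1) / fold - 1 was taken in each library. The strongest peak of 37 of 48 libraries lay on chromosome 2 between 98666225 and 98667519, and at most 0.660% of intervals were identical between libraries of a state.

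Lists of different length cannot be compared peak by peak, so the 28000 strongest peaks by the last column were kept, which is the 12th percentile of the list lengths rounded down to a whole 1000. Clones with a shorter list in either state (3, 10, 21 and 22) were left out, which kept 20 clones and 40 libraries. Peaks outside chromosomes 1 to 19, X and Y were dropped. Peaks of all libraries that overlapped by 1 bp or more were merged into regions. A kept peak was assigned to the protein-coding gene with the nearest annotated gene end within 50 kb of its midpoint. The gene table, for the same mm10 assembly, held 21887 protein-coding genes and no strand, so both gene ends were used in place of transcription start sites. This departs from the plan. The planned test of sequence motifs was not run because no genome sequence was at hand.

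Regions found in at least 3 and lacking in at least 3 libraries were tested with a two-sided exact McNemar test over clones. Genes with a kept peak in at least 3 libraries were tested with a two-sided exact paired sign-flip permutation test on the number of kept peaks. Gene lists were tested with a paired sign-flip permutation test of the mean over list genes, exact in sets of up to 11 clones and with 100000 draws over 20 clones. The same test was used for the gene-end share, the similarity within states and the list lengths. Similarity was the Jaccard index over regions. Clonal partners were compared with a one-sided permutation of clone labels (100000 draws, smallest p 1e-05). Regions shared by partners were tested with a one-sided Fisher's exact test where at least 4 clones had and at least 4 lacked a peak in each state. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05. State regions called in clones 1 to 13 were also looked up in libraries outside the calls.

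The comparisons, the gene lists, the rule for named genes and the first alternatives were chosen before the data were examined. The 16 lists were monocyte and macrophage identity, stem and progenitor, primary granule, mature neutrophil, dendritic cell, antigen presentation, inflammatory response, interferon response, phagocytosis and lysosome, adhesion and migration, erythroid and megakaryocyte, lymphoid, mast cell with basophil and eosinophil, cell cycle, housekeeping, and myeloid transcription factors. Of their 256 entries 254 matched the gene table. Named genes were the 12 with the largest mean difference in each direction among those past the threshold, without predicted genes, up to 4 members per list, and Hoxb8, Csf1r, Spi1, Cebpa, Irf8 and Kit. Other list members that passed in clones 1 to 13 were named as well, some beyond that rule, after their values were seen. Named regions were the 5 strongest in each direction, and up to 10 for clonal sharing.

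The split into clones 1 to 13 and clones 15 to 26, all results within the sets, the handling of clones 3 and 10, and leaving out clones 16 and 20 or clone 18 were chosen after seeing the data. Alternatives were all deposited peaks, 14000 peaks, all 24 clones at 11500 peaks, lists that differed by less than 2 times, merging at 100 bp, 500 bp bins, no replicate block, 10 kb to a gene end, presence per gene, and support of 6 libraries. The pairing by clone was kept as a block in all main tests, and whether it holds was examined by the similarity of clonal partners.

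The tests were tried on simulated data, drawn independently per region or gene with the same rate in every clone of a state. The real clones differed by set, so the shares recovered and the false calls need not hold for the pooled comparison. With 200 changed regions over 20 clones, 84.5% were recovered where 10% against 90% of clones had a peak and 0% where 30% against 70% had one, with 0 false calls. Of 200 genes, 0.5% were recovered at a 2-fold and 78% at a 4-fold change, the latter with 2 false calls. In the 11 clones numbered 1 to 13, 0% passed after adjustment. There 200 changes were too few for any to pass, so this 0% says nothing about power. With the larger change, 96% of regions and 93.5% of genes had an unadjusted p under 0.05. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.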

Results

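Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in mouse ER-Hoxb8 cells. These are bone marrow progenitors held in an immature state by an oestrogen-dependent form of the homeobox factor Hoxb8, and they differentiate when that factor is switched off. Each of 24 clones was given as a pair of libraries, 1 from progenitors and 1 from monocytic cells, which made 48 peak lists with 3312319 peaks in total. The lists held between 11592 and 356753 peaks. Clones numbered 1 to 13 and clones numbered 15 to 26 differed so much in their lists that most comparisons are also given for each set, a split chosen after the data were seen. In the 28000 strongest peaks of each list, 20 clones could be compared, 11 of them numbered 1 to 13 and 9 numbered 15 to 26. All p-values measure the spread between these clones only.

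Progenitor lists held 42460 ± 10440 peaks (SD, n = 13) in clones 1 to 13 and 157060 ± 124422 (n = 11) in clones 15 to 26, against 37696 ± 9039 and 49331 ± 27432 in the monocytic lists. Over 24 clones the progenitor list was longer in 19, by 1.53 times on the geometric mean (log10 difference, monocytic minus progenitor, -0.185 ± 0.442, two-sided permutation p = 0.0519). Within clones 1 to 13 it was longer in 10 of 13, by 1.12 times (p = 0.011, exact), and within clones 15 to 26 in 9 of 11, by 2.22 times (p = 0.0967, exact). Read depth is not given in the sources used here. The lowest background pileup implied by the peaks of a library averaged 3.21 ± 0.606 in the progenitors and 2.66 ± 0.361 in the monocytic cells of the 11 compared clones numbered 1 to 13. In the 9 numbered 15 to 26 it averaged 0.923 ± 0.846 in progenitors and 2.98 ± 0.638 in monocytic cells.

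Peaks close to annotated gene ends, where promoters lie, made up shares of the strongest peaks that differed between the states of clones 1 to 13 by less than the spread between clones. The share within 1 kb of a gene end was 33.6% ± 0.529 (SD, n = 11) in progenitors and 33.4% ± 0.769 in monocytic cells (exact two-sided sign-flip p = 0.463, higher in monocytic cells in 4 of 11). The difference there turned and passed with all deposited peaks (2.37 points, exact p = 0.0107) and with 14000 (0.665 points, exact p = 0.0342). In clones 15 to 26 it was 9.27% ± 4.66 (n = 9) in progenitors and 26.6% ± 4.19 in monocytic cells, higher in 9 of 9 (exact p = 0.00391, the smallest this test can give for 9 clones). Pooled over 20 clones, the difference of 7.73 percentage points (p = 0.00303, permutation, higher in 13 of 20) came with -0.134 points in the first set and 17.3 in the second. A permutation of the set labels gave p = 2e-05 for the difference between the sets (adjusted p = 0.000113 over this share and the 16 gene lists). The sets were split after their lists were seen to differ, so this p describes the split and is no evidence for it. Of the 13842 regions with a peak in every library of the 11 clones, the progenitors of clones 15 to 26 held 18.1% ± 10.2 (SD, n = 9) and their monocytic cells 52.7% ± 11.1.

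**Figure D1:**
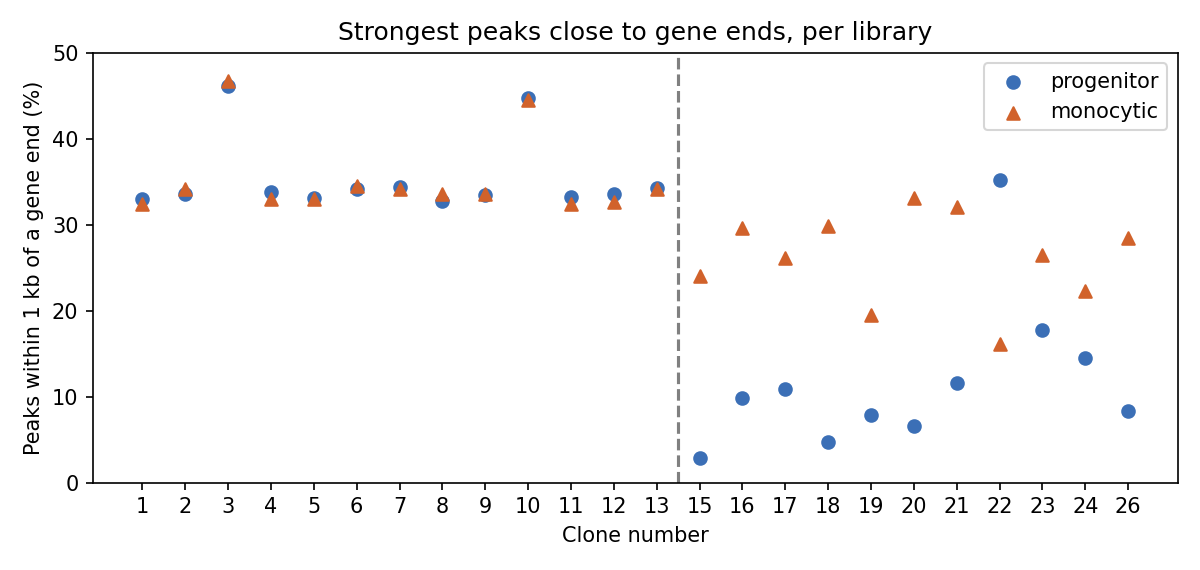
Share of the strongest peaks (at most 28000 per list) whose midpoint lay within 1 kb of an annotated gene end, in percent, for each library by clone number, with circles for progenitors, triangles for monocytic cells and a dashed line between clones 13 and 15. The 11 compared clones numbered 1 to 13 averaged 33.6% and 33.4%, and the progenitors of the 9 numbered 15 to 26 averaged 9.27%.

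The first question the pairing answers is which sites differ between progenitors and the monocytic cells of the same clone. The genes with the largest gain in the monocytic cells of clones 1 to 13 came first. Sorl1, a sorting receptor (chromosome 9, 41964709 to 42124297, mm10), rose from 2.55 ± 1.13 to 7.82 ± 1.89 kept peaks per gene (SD, n = 11). Ccr1, a chemokine receptor of myeloid cells (chromosome 9, 123962126 to 123968692), rose from 5.18 ± 1.40 to 9.18 ± 1.08, and Atp8b4, a lipid-flippase family member, from 8.09 ± 0.831 to 13.2 ± 1.17. Gca, which encodes the granulocyte protein grancalcin, rose from 1.82 ± 0.603 to 5.55 ± 1.04, Gsr, glutathione reductase, from 2.36 ± 0.505 to 6.09 ± 0.701, and Pdcd1lg2, a ligand of the receptor PD-1, from 2.36 ± 1.12 to 6.09 ± 1.38. The other named genes that rose were Exoc2, St3gal1, Ina, Rcbtb2, Mreg and Susd6, with mean gains from 3.64 peaks for Susd6 to 4.55 for Exoc2.

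Other genes lost peaks in the monocytic cells of clones 1 to 13. Arpp21 (chromosome 9, 112065091 to 112236288) fell from 6.27 ± 1.35 to 1 ± 0.775 kept peaks (SD, n = 11). Tnfrsf1b, a receptor of tumour necrosis factor, fell from 8.64 ± 0.809 to 4.45 ± 0.688, Ackr2, an atypical chemokine receptor, from 4.82 ± 0.405 to 0.727 ± 1.01, and Alpl, alkaline phosphatase, from 4.55 ± 1.44 to 0.636 ± 0.924. Gbp10, a guanylate-binding protein, fell from 4.64 ± 0.809 to 1.18 ± 1.25. Itga9, an integrin subunit, fell from 6.64 ± 0.809 to 2.91 ± 0.831, and Rtn4, Lrrc1, Ano6, Lrrk1, Lclat1 and Katnal1 fell as well. Of 14196 genes tested in these clones, 1329 passed an adjusted p of 0.05 in the two-sided exact paired sign-flip test, 734 higher in monocytic cells and 595 higher in progenitors. At an unadjusted p under 0.05 there were 1747 and 1574. The smallest p that 11 clones can give is 0.000977, which became an adjusted p of 0.0332, the value of these 24 genes, each changed in the same direction in 10 or 11 of the 11 clones. These counts were 0 and 0 in the exact sign-flip test when only peaks within 10 kb of a gene end were counted (unadjusted, 1216 and 1007), or only presence of a peak (414 and 403). All deposited peaks in place of the strongest gave 372 and 1045 with 544 genes called both ways, 14000 peaks gave 284 and 219 with 131 called both ways, and adding clones 3 and 10 at 18000 peaks gave 321 and 234 with 258. With 14000 peaks, Sorl1, Gsr, Mreg, Arpp21, Alpl, Rtn4, Lrrk1, Gbp10 and Lclat1 still passed and the others of the 24 did not. Gca then had a difference of 0 (adjusted p = 1), or 0.615 (0.271) with clones 3 and 10, and Rcbtb2 -0.909 (0.561). Of the genes that passed with 14000 peaks, Sorl1 (3.55, adjusted p = 0.0628), Gsr (1.27, 0.246), Mreg (2.91, 0.0628) and Lrrk1 (-2, 0.0628) did not pass the sign-flip test with all deposited peaks. Gsr (0.0565) and Lrrk1 (0.115) also did not pass with clones 3 and 10. Within 10 kb of a gene end the smallest adjusted p of the sign-flip test was 0.0518, reached by Sorl1 (2.09) and Atp8b4 (2.36) among others. Ccr1 (0.455, adjusted p = 0.292), Exoc2 (0.364, 0.973) and Mreg (0.273, 0.974) kept little of their gain there. Most of the gain of these last genes thus lay between 10 and 50 kb from a gene end.

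Genes that define the system itself were less clear. Hoxb8 had 0.364 ± 0.505 kept peaks in progenitors and 1.18 ± 0.874 in monocytic cells (n = 11, adjusted p = 0.2), and Csf1r, the receptor of the monocyte growth factor, had 1 and 2.18 ± 0.982 (adjusted p = 0.0606). Spi1, which encodes the myeloid factor PU.1, had 4.55 ± 0.522 and 5.55 ± 0.820 (adjusted p = 0.0902). Cebpa had 4.09 and 4.64 (adjusted p = 0.568), Irf8 2.91 and 3 (adjusted p = 1) and Kit, the receptor of stem cell factor, 2.36 and 2.27 (adjusted p = 1). Over 20 clones, Spi1 rose from 2.70 to 3.75 (adjusted p = 0.00813, higher in 15 and lower in 0 clones) and Hoxb8 from 0.25 to 1.15 (adjusted p = 0.0331, higher in 13, lower in 1). Neither passed with 14000 peaks (0.25 and 0.2, adjusted p = 0.546 for both), with 24 clones at 11500 peaks (0.333, 0.39 and 0.125, 0.559) or with all deposited peaks (-1.1, 0.247 and 0.2, 0.512). The same held with lists that differed by less than 2 times (adjusted p = 0.088 and 0.127). Spi1 was also lost without the pairing as a block (0.535) and Hoxb8 without clones 16 and 20 (0.0681).

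Of 16 gene lists, 8 rose in the monocytic cells of clones 1 to 13 and 4 fell. When only presence of a peak per gene was counted, 2 were higher (monocyte and neutrophil) and 2 lower (lymphoid and erythroid). The calls of the inflammatory (0.0152, adjusted p = 0.892), adhesion (0, 1), primary granule (0.0636, 0.141), stem and progenitor (-0.026, 0.141) and dendritic cell (-0.014, 0.942) lists were then lost. The phagocytosis (-0.0455, adjusted p = 0.141), mast cell (-0.0303, 0.892) and myeloid transcription factor (-0.00909, 0.889) lists turned. The mature neutrophil list gained most, 0.829 ± 0.313 peaks per gene (n = 11, higher in 11 of 11, adjusted p = 0.0026 over the lists, exact two-sided sign-flip). Of its 16 tested genes 5 rose, 0 fell and 11 did not pass (11 up and 1 down when adjusted over the list alone). S100a9 and S100a8, the subunits of calprotectin, rose from 1 to 3.64 ± 0.505 and from 0 to 2 in every clone, and the granule gene Ngp rose from 0 to 1.82 ± 0.405. The monocyte and macrophage list rose by 0.610 ± 0.309 (11 of 11, adjusted p = 0.0026). Of its 22 genes 6 rose, 1 fell and 15 did not pass (9 up and 1 down adjusted over the list alone). Ly6c2, a surface marker of classical monocytes, rose from 1.36 ± 0.505 to 3.91 ± 1.14, the integrin gene Itgam from 2.73 ± 1.19 to 5.18 ± 1.25 and the lipopolysaccharide co-receptor gene Cd14 from 0 to 2.09 ± 0.539. Treml4, Cx3cr1 and Cd68 rose too, and Klf4, a factor needed for monocyte formation, fell from 2.91 ± 0.539 to 1.45 ± 0.522.

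The inflammatory list rose by 0.621 ± 0.310 (11 of 11, adjusted p = 0.0026, exact), with 7 of 18 genes up and 0 down (8 and 1 adjusted over the list alone). Il1b, which encodes interleukin-1 beta, rose from 3.45 ± 0.820 to 5.18 ± 0.405, and the bacterial-product receptor gene Tlr4 from 1.45 ± 0.522 to 3.45 ± 1.13. Tlr2, Nos2, Nlrp3, Tnfaip3 and Il1rn rose as well. The adhesion and migration list rose by 0.523 ± 0.166 (11 of 11, adjusted p = 0.0026), with Ccr1 and Sirpa up among 16 genes (3 up and 0 down adjusted over the list alone). The phagocytosis and lysosome list rose by 0.404 ± 0.250 (11 of 11, adjusted p = 0.0026), where Ctsb, Gpnmb and Trem2 rose and the scavenger receptor gene Marco fell from 1.18 ± 0.405 to 0 (3 up and 1 down adjusted over the list alone). The primary granule list rose by 0.382 ± 0.331 (10 of 11, adjusted p = 0.00781), with Serpinb1a and Igsf6 up among 9 genes (2 up and 1 down adjusted over the list alone). The myeloid transcription factor list rose by 0.332 ± 0.299 (10 of 11, adjusted p = 0.0104). Cebpd, Zeb2 and Fli1 rose and Bach1 and Gfi1b fell among its 20 genes (7 up and 3 down adjusted over the list alone). The mast cell, basophil and eosinophil list rose by 0.280 ± 0.308 (8 of 11, adjusted p = 0.0208), where the histamine-forming enzyme gene Hdc and Il1rl1 rose (2 up and 0 down adjusted over the list alone). This list passed in the other direction with all deposited peaks (-0.348, adjusted p = 0.0223) and gave 0.0455 (adjusted p = 0.487) with 14000 peaks. The myeloid transcription factor list gave -0.364 (adjusted p = 0.0611) and 0.0682 (0.346), and the adhesion and migration list -0.358 (0.0608) with all deposited peaks.

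The dendritic cell list fell by 0.49 ± 0.169 peaks per gene (lower in 11 of 11, adjusted p = 0.0026, exact). Tcf4, a factor of plasmacytoid dendritic cells, fell from 3.18 ± 1.17 to 1.27 ± 0.467, and Ccr7 and Bst2 fell among 12 genes (0 up and 4 down adjusted over the list alone). With 14000 peaks this list gave -0.0559 (adjusted p = 0.346) and the lymphoid list -0.0398 (0.159). The stem and progenitor list fell by 0.372 ± 0.363 (lower in 9 of 11, adjusted p = 0.0142), with Adgrg1 down from 7.82 ± 0.874 to 5 ± 1.48, the Hox cofactor gene Meis1 from 6.09 ± 0.302 to 4.82 ± 0.405, and Ikzf2 down too (0 up and 4 down adjusted over the list alone). The lymphoid list fell by 0.347 ± 0.166 (10 of 11, adjusted p = 0.00446), where Rag2, a recombinase subunit of lymphocytes, fell from 1.45 ± 0.688 to 0 (0 up and 1 down adjusted over the list alone). The erythroid and megakaryocyte list fell by 0.247 ± 0.195 (10 of 11, adjusted p = 0.0109), with Epor, the erythropoietin receptor gene, down and Vwf up (1 up and 3 down adjusted over the list alone). The other lists did not pass: housekeeping -0.159 ± 0.212 (adjusted p = 0.0601, with Ywhaz down of 12, 0 up and 1 down adjusted over the list alone), cell cycle -0.0625 ± 0.134 (0.223, with Cdkn1a down of 16, 0 and 1 adjusted over the list alone), antigen presentation 0.0519 ± 0.313 (0.679, 0 genes past, 0 also adjusted over the list alone) and interferon response 0.0140 ± 0.164 (0.889, with 1 gene up of 8, 1 and 0 adjusted over the list alone). Antigen presentation passed with 14000 peaks (0.149, adjusted p = 0.00694) and with clones 3 and 10 (0.258, 0.00488). Interferon response passed with 14000 peaks (0.0769, 0.025) and in the other direction with all deposited peaks (-0.182, 0.0312). Housekeeping passed with all deposited peaks (-0.409, 0.0223) and cell cycle with clones 3 and 10 (-0.0962, 0.0156). With all deposited peaks in place of the strongest, the neutrophil list alone stayed higher (adjusted p = 0.00391) and 7 lists were lower, and the monocyte list gave 0.292 (adjusted p = 0.0611).

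**Figure D2:**
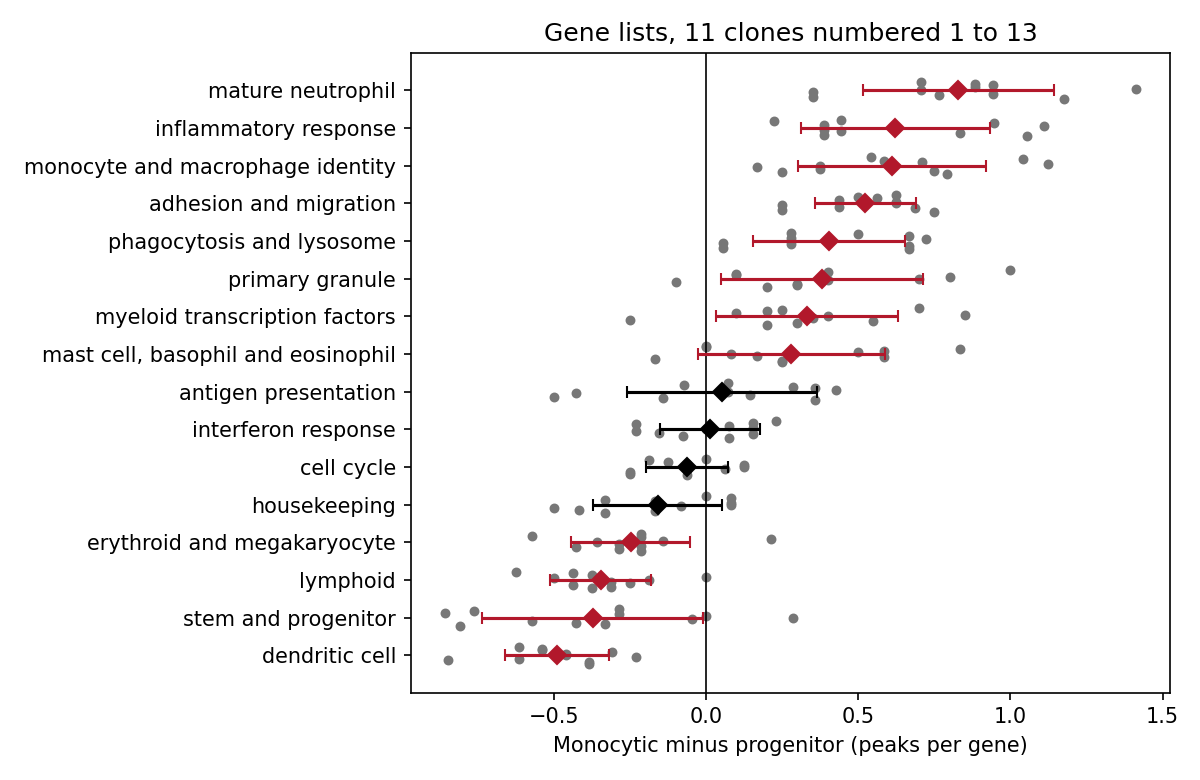
Difference in kept peaks per gene, monocytic minus progenitor, for each of the 16 gene lists in the 11 compared clones numbered 1 to 13, with a grey point per clone, diamonds for the mean, bars for 1 SD, and red for lists past an adjusted p of 0.05. The mature neutrophil list had the highest mean, 0.829, and the dendritic cell list the lowest, -0.490.

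Over 20 clones, 876 of 19316 genes passed, 735 higher in monocytic cells and 141 higher in progenitors (unadjusted, 2900 and 912). Ankrd33b rose from 1.80 ± 0.951 to 5.2 ± 1.06 kept peaks (n = 20, adjusted p = 0.00567, higher in 20 of 20), Nr3c1, the glucocorticoid receptor gene, from 2.70 ± 1.95 to 6 ± 2.05, and Amotl2 from 0.70 ± 0.733 to 3.55 ± 1.54. Arpp21 fell from 4.75 ± 2.22 to 1.25 ± 0.851 (adjusted p = 0.00813, lower in 16, higher in 1) and Pdzph1 from 3.25 ± 1.52 to 0.70 ± 0.923 (adjusted p = 0.00567, lower in 19, higher in 0). Sfi1 had the largest gain, from 6.55 ± 3.25 to 11.2 ± 3.69, but did not pass with 14000 peaks (3.7, adjusted p = 0.0727), with 24 clones at 11500 peaks (2.62, 0.178), within 10 kb (1.4, 0.101) or with all deposited peaks (1.35, 0.267). Sorl1, Actn1, Ccr1, Retreg1, Atrnl1, Gsr, Exoc2 and Itpkb also rose, and Tnfrsf1b, Ackr2, Alpl, Gbp10, Chl1, Ikzf2, Col19a1, Arhgef10l, Ackr3 and Angpt1 fell. Within 10 kb of a gene end, Ankrd33b had 0.4 (adjusted p = 0.449), Arpp21 -0.8 (0.163) and Pdzph1 -0.25 (0.553), and with 14000 peaks Amotl2 had 0.75 (0.0645). With all deposited peaks Ankrd33b (-1.65, adjusted p = 0.353), Nr3c1 (-2.1, 0.25) and Amotl2 (-0.3, 0.895) turned and did not pass. With all deposited peaks there were 8 monocytic-higher and 8682 progenitor-higher genes, and with presence per gene 0 passed the exact sign-flip test (unadjusted, 1229 and 419). Genes called both over 20 clones and in clones 1 to 13 numbered 378 higher in monocytic cells and 84 higher in progenitors.

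In clones 15 to 26, 0 of 18663 genes passed the exact sign-flip test, and 1741 higher and 239 lower in monocytic cells had an unadjusted p under 0.05. There, 8 of 16 lists were higher in monocytic cells and 0 lower, among them lists with little tie to monocytes. The housekeeping list gained 0.583 ± 0.257 peaks per gene and the cell cycle list 0.583 ± 0.401 (n = 9, higher in 9 of 9 each, exact adjusted p = 0.0125). The dendritic cell list gained 0.385 ± 0.176 and the antigen presentation list 0.349 ± 0.219 (9 of 9 each, exact adjusted p = 0.0125), and the erythroid, interferon, phagocytosis and myeloid factor lists passed too. The monocyte list (0.352, higher in 7 of 9, exact adjusted p = 0.0625) and the neutrophil list (0.556, 8 of 9, 0.0673) did not pass there. Nor did the inflammatory (0.333, 0.0673), adhesion (0.188, 0.344) and primary granule (0.1, 0.6) lists. The progenitor libraries of this set also held fewer peaks near gene ends, 9.27% against 26.6%. A permutation of the set labels gave an adjusted p of 0.000113 for the difference between sets in the housekeeping and dendritic cell lists and 0.00325 in the stem and progenitor list, while the monocyte list (0.151) and the neutrophil list (0.308) did not pass it. These values too describe a split chosen after the data were seen. Pooled over 20 clones, 10 lists were higher and the lymphoid list was lower, but with all deposited peaks 15 were lower and the other, mature neutrophil, did not pass (-0.524, adjusted p = 0.219), and with presence per gene 5 were higher and 1 lower. The pooled erythroid and mast cell lists, which did not pass, had means above 0 (0.0107 and 0.0708) and median members below 0 (-0.025 and -0.10).

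Single regions separated the states completely in clones 1 to 13. A region 14 bp from S100a8 (chromosome 3, 90668673 to 90669441) had a peak in 11 of 11 monocytic libraries and 0 of 11 progenitor libraries, as had a region within Rasa1, 81 bp from its end (chromosome 13, 85288996 to 85289815). The same held for regions near Rnf112 (chromosome 11, 61469244 to 61469815), Zfyve26 (chromosome 12, 79235187 to 79236008) and Col4a2 (chromosome 8, 11403677 to 11404289). Found in 11 of 11 progenitor and 0 monocytic libraries were regions within Adck1 (chromosome 12, 88413147 to 88413808), Tcerg1l (chromosome 7, 138246331 to 138247207) and Rcsd1 (chromosome 1, 165679940 to 165680550). Regions on chromosome 5 (131600203 to 131600999) and chromosome 9 (81073227 to 81073773), with no gene end within 50 kb, did the same. Each had p = 0.000977, the smallest that the two-sided exact McNemar test can give for 11 clones, and an adjusted p of 0.0259. Of 24609 regions tested, 2166 were higher in monocytic cells and 2155 in progenitors, and 535 and 303 had a kept peak in all libraries of 1 state and none of the other. With all deposited peaks, 1331 and 2705 regions passed. In 11 clones a region or gene can pass the adjustment only if many reach a p near the smallest possible, so the calls rest on many having changed together. The 200 changes simulated at a time were too few for any to pass.

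Over 20 clones 2180 of 53988 regions passed, 1337 higher in monocytic cells and 843 in progenitors (unadjusted, 8299 and 4152). The region beside S100a8 (chromosome 3, 90668631 to 90669441) had a peak in 19 of 20 monocytic and 1 of 20 progenitor libraries (adjusted p = 0.0412), a region near Corin (chromosome 5, 72259143 to 72259833) in 17 and 0, a region within Anp32b (chromosome 4, 46451280 to 46452675) in 19 and 2, and a region near S100a7a (chromosome 3, 90659239 to 90660155) in 18 and 1. A region on chromosome 12 (82524675 to 82525552), with no gene end within 50 kb, had 18 and 1. Regions within Adck1 (chromosome 12, 88412799 to 88413808) and Ptk2b (chromosome 14, 66266096 to 66266726), and on chromosomes 18 (45476858 to 45477772) and 8 (54420315 to 54421244), were found in 13 progenitor and 0 monocytic libraries (adjusted p = 0.0435). A region on chromosome 4 (55586124 to 55586686) was found in 12 and 0. In each of these 5 progenitor regions the peaks included all 11 progenitors numbered 1 to 13. In clones 15 to 26 alone, 0 of 24209 regions passed the exact McNemar test, and 4160 higher and 2 lower in monocytic cells had an unadjusted p under 0.05. Over 20 clones, 0 regions passed the same test in 500 bp bins (unadjusted, 7862 and 4322) or with all deposited peaks (4262 and 11039). Without clone 18, whose progenitor peaks had a median pileup of 1, 676 and 347 regions, 609 and 138 genes and 8 lists (7 higher, 1 lower) passed, and the antigen presentation (adjusted p = 0.0574), interferon response (0.0586) and cell cycle (0.0889) lists no longer did.

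The regions called in clones 1 to 13 were then looked up in every library. With each clone left out of the calls and its lists shortened to 18000 peaks, the monocytic-higher regions made up 0% to 1.36% of the state regions found in the 11 progenitor libraries and 96.3% to 100% in the monocytic ones. In clone 3, left out of the comparisons for its short lists, this share was 15.8% in the library labelled progenitor and 15.3% in the library labelled monocytic, and in clone 10 it was 16.9% and 15.3%. The sets of regions were unlike: 1905 to 3772 called in the other 10 clones for each of the 11, and 4321 for every other clone. With longer lists, of the same length in both states of a clone (18611 peaks in clone 3, 20004 in clone 10 and at most 28000 in the others), the direction was counted. Of 417 called regions found in 1 library of clone 3 only, 196 followed the called direction (47.0%, 95% exact Clopper-Pearson interval 42.1% to 51.9%). In clone 10 it was 238 of 502 (47.4%, 43.0% to 51.9%). These 4 libraries held 92.2% to 93.6% of the 13842 regions found in every library of the 11 clones. In clone 20 the order was turned, with 93.7% in the library labelled progenitor and 36.8% in that labelled monocytic at 18000 peaks, and 41 of 305 regions in the called direction at 28000 (13.4%, 9.82% to 17.8%). The share was also higher in the library labelled progenitor in clone 21 (88.4% against 74.6%), clone 16 (84.1% against 81.7%) and, at 11592 peaks, clone 22 (60.9% against 40%). Clone 16 had 142 of 301 (47.2%, 41.4% to 53.0%), clones 21 and 22, left out for short lists, had 35.1% and 36.2%, and clones 17, 19, 23 and 24 had 72.6%, 58.6%, 69.4% and 66.7%, with 51.3%, 63.9%, 58.3% and 31.1% in the regions called progenitor-higher. Clones 15, 18 and 26 had 91.2%, 96.3% and 92.3%, but only 38.6%, 54% and 72.6% in the regions called progenitor-higher. The intervals cover counting error only. Without clones 16 and 20, the pooled counts were 1445 and 853 regions, 701 and 143 genes, and 7 lists higher and 1 lower. The antigen presentation (adjusted p = 0.0601, paired sign-flip), interferon response (0.0609) and cell cycle (0.147) lists then no longer passed.

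**Figure D3:**
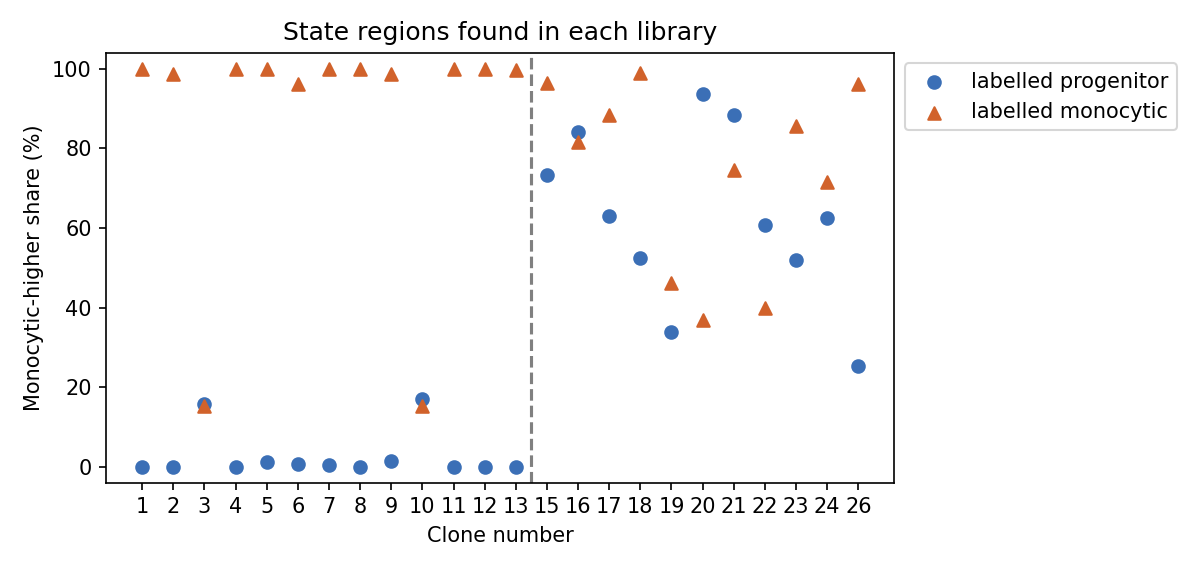
Share of monocytic-higher regions among the state regions found in each library, in percent, by clone number, with circles for libraries labelled progenitor, triangles for those labelled monocytic and a dashed line between clones 13 and 15, each list shortened to at most 18000 peaks and each of the 11 compared clones left out of its own calls. Both libraries of clones 3 and 10 lay between 15.3% and 16.9%, apart from the 11 compared clones of their set (0% to 1.36% and 96.3% to 100%). The 11 were scored on regions called in the other 10 clones, and every other clone on the 4321 regions called in all 11.

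Within a state, clones 1 to 13 resembled each other more as progenitors than as monocytic cells. The mean Jaccard index, the share of regions 2 libraries have in common, was 0.744 ± 0.0438 over 55 pairs of progenitors and 0.694 ± 0.0518 over 55 pairs of monocytic libraries (exact two-sided p = 0.0186). The order was the other way in clones 15 to 26, 0.0223 ± 0.0149 and 0.178 ± 0.0349 over 36 pairs (exact p = 0.00391), and pooled over 20 clones it was 0.249 and 0.332 (permutation p = 0.0122). The difference within clones 1 to 13 shrank to 0.0102 (p = 0.493) with the strongest 14000 peaks. Without clones 16 and 20 the pooled difference, progenitor minus monocytic, was -0.0675 (p = 0.056).

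The pairing also asks whether a clone keeps its own accessible sites as it matures. In clones 1 to 13 the monocytic library resembled the progenitor library of its own clone more on average than those of other clones, with a mean Jaccard index of 0.604 ± 0.065 (SD, n = 11) against 0.584. The one-sided permutation p was 1e-05, the smallest that 100000 permutations can give. Seen from the progenitor library, the own partner was the nearest monocytic library in 4 of 11 clones, and in 7 of 11 once each library's mean similarity was removed. In clones 1, 8, 11 and 12 the own monocytic library was less alike than the mean of those of other clones (0.537 against 0.579, 0.5 against 0.536, 0.534 against 0.582 and 0.571 against 0.605), and in clone 11 it ranked last. In clones 15 to 26 the values were 0.0488 ± 0.0328 and 0.0493 (n = 9, one-sided permutation p = 0.646). Over 20 clones they were 0.354 and 0.239, and with labels permuted within the sets 0.354 and 0.344 (p = 1e-05 for both, the smallest possible).

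Clone pairs that were alike as progenitors were alike as monocytic cells in clones 1 to 13. Clones 1 and 11 were the most alike pair in both states, with 0.857 and 0.797. Over the 55 pairs of these 11 clones Pearson's r was 0.530 (permutation of clones p = 0.00168) and Spearman's rho 0.547 (p = 0.0018), and without clones 8 and 12, farthest from the median, r was 0.655 (p = 0.00241). Pairs of clones share clones and are not independent, which the permutation of whole clones takes into account. The relation was computed for this set only.

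**Figure D4:**
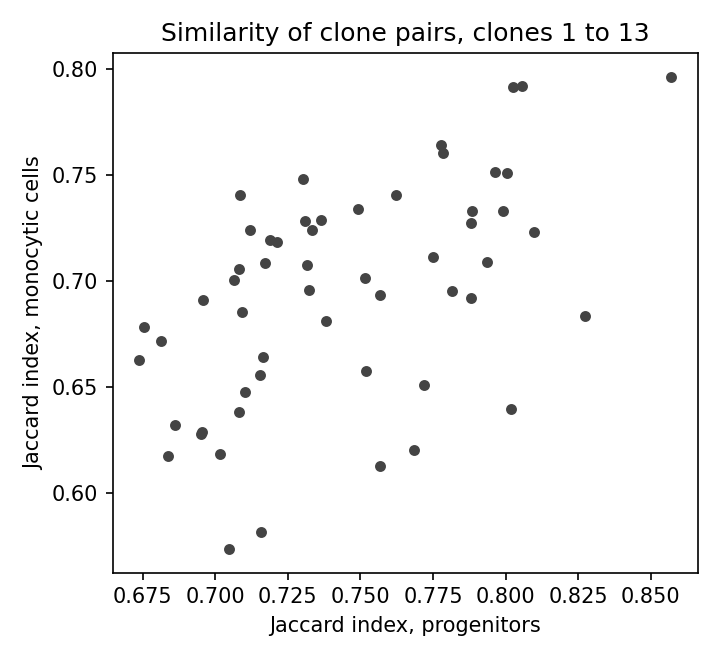
Jaccard index between progenitor libraries (horizontal axis) and between monocytic libraries (vertical axis) for each of the 55 pairs of the 11 compared clones numbered 1 to 13, a point per pair, both axes without unit. Pearson's r was 0.530, and clones 1 and 11 had the highest values, 0.857 and 0.797.

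Some regions had a kept peak in the same clones in both states. Regions near Hook1 (chromosome 4, 95966875 to 95967675), Chst13 (chromosome 6, 90324987 to 90325445), Ppfibp2 (chromosome 7, 107594378 to 107595355) and Klrb1b (chromosome 6, 128807621 to 128807958), and a region on chromosome 7 (60244191 to 60244646), each had a peak in both libraries of 6 clones and in neither library of the other compared clones of the set. Regions near Usp6nl (chromosome 2, 6436032 to 6436492), Gcc1 (chromosome 6, 28409916 to 28410461) and Prrt3 (chromosome 6, 113494186 to 113494980), and another on chromosome 7 (39655105 to 39655636), were shared in 5 clones in the same way. All had p = 0.00216 in the one-sided Fisher's exact test (22 regions had this smallest p). Of 1485 regions tested in clones 1 to 13, 0 passed after adjustment (smallest adjusted p = 0.0918) and 264 had an unadjusted p under 0.05. The other set had 0 of 81 regions past the exact test and 0 with an unadjusted p under 0.05.

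Over 20 clones 13062 of 17551 regions passed this one-sided Fisher's exact test, and the named ones followed the sets. Regions near Msrb2, Shld1, Zfp217, Raver2, Sfpq, Man1c1, AB010352, Pepd and Gins2, and 1 on chromosome 9 (23570082 to 23570629), each had a peak in both libraries of 10 of the 11 clones numbered 1 to 13 and in 0 of the 9 others (p = 5.41e-06, reached by 23 regions). The pooled count does not separate clones within a set, where 0 regions passed, and among the 13 clones whose lists differed by less than 2 times it was 0 in Fisher's exact test (739 at an unadjusted p under 0.05).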

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

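All tests in this part on clones 3 and 10, on the excess of monocytic-higher genes and on weak peaks were chosen only after the result was seen, as was the permutation of shared regions. The progenitor library of clone 15 held 251 peaks outside chromosomes 1 to 19, X and Y, which no comparison used. It was also the longest list, with 356753 peaks, so the count is no sign of a larger share. The progenitors of clone 10, for instance, held 103 such peaks among 20004.

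Over 20 clones, 83.9% of the called genes were monocytic-higher. In clones 1 to 13 it was 55.2%, but 14196 genes were tested there in 11 clones and 19316 over 20, and 378 monocytic-higher genes were called in both, so a gain that all clones share is neither shown nor excluded. Progenitor libraries of clones 15 to 26 that missed shared regions may account for the excess. Regions found in every library of clones 1 to 13 were recovered 34.6 percentage points less often in progenitors than in monocytic cells of clones 15 to 26, in 9 of 9 clones (exact p = 0.00391). These progenitor libraries were weaker in background pileup (mean 0.923 against 2.98) but not in every measure. The median fold of their kept peaks averaged 8.16 ± 6.62 against 4.89 ± 0.686 in monocytic cells (SD, n = 9), and was lower in the progenitors of clones 18, 23 and 24 only. Chance is argued against for the counts themselves, since 1 of 100 swaps of the state labels within clones, the real one, gave as many. Over 20 clones there were 2180 regions and 876 genes against 0 and 0 in the highest other swap. In clones 1 to 13 there were 4321 and 1329 against 0 and 0. In 11 clones smaller numbers of changes cannot pass the adjustment, so a swap reaches 0 easily. With 100 swaps the support can be no finer than 1 in 100. A biological difference between the sets of clones was not tested and stays open.

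The libraries of clones 3 and 10 did not differ in the regions called in clones 1 to 13. Short and weak lists stay open: each of the 11 clones, left out of the calls and shortened to 18000 peaks, kept at least 99.7% of regions in the called direction, but its peaks stayed stronger (median fold 14.7 or more, against at most 8.83 in clones 3 and 10). Cells of both states in each library could give the shares seen. In the 4 libraries these were no lower than 15.3% and lay between the ranges of the other progenitor and monocytic libraries at 18000 peaks. The sets of regions differed, however. Each of the 11 clones was scored on 1905 to 3772 regions called in the other 10, and clones 3 and 10 on 4321. How much of the gap comes from that was not tested. The gap depends on that length: at 28000 peaks the range of the 11 progenitor libraries was 0.249% to 12.9%. For clones 3 and 10, 18000 peaks are most of the list (18611 to 20496 peaks). A progenitor library in the place of the monocytic one cannot be told apart from cells of both states. The highest share in the libraries labelled monocytic, 15.3%, lay outside the ranges of both states at 18000 peaks. A clone that did not differentiate is a biological alternative that was not tested.

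Partners of a clone resembled each other on average within clones 1 to 13. Library strength shared by both lists of a clone was examined only through the similarity of clone pairs. The relation of both similarity matrices kept r = 0.480 (permutation p = 0.00158) after list length, fold and gene-end share were regressed out. The resemblance of own partners was not regressed, and background pileup and the unknown read depth were left out, so shared library strength stays open. With 14000 peaks, 109 regions were shared at an unadjusted p under 0.05, against at most 45 in 99 permutations. Weak peaks near the cutoff of the lists stay open, since a shorter list only moves the cutoff. With 28000 peaks, the count of 264 regions was reached by 1 of 100 labellings, the real one (median of the others 21, highest 92). This argues against chance for the count alone. Single regions among the 264 may still be chance, since 0 of 1485 passed after adjustment. Sites that a clone keeps through maturation are a hypothesis, which a difference in the DNA of the clones or in how both lists of a clone were prepared leaves open.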

How the results depend on the processing

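Alternatives within the clone sets, leaving out clones 16 and 20 or clone 18, and all those of clones 1 to 13 were chosen after seeing the data, the others before. Where a value changed, the cause was not tested. Values are mean differences in kept peaks, monocytic minus progenitor, unless a count is named. Of the values for single genes over 20 clones, 194 kept direction and side of the threshold, 109 lost the threshold and 27 turned, and for lists it was 87 kept, 27 lost, 13 gained and 33 turned. In clones 1 to 13 it was 92, 79, 7 turned and 2 gained for genes and 49, 15, 11 turned and 5 gained for lists. The mature neutrophil list kept its direction and threshold in clones 1 to 13 under each of the 5 settings tried. The motif alternatives were not run, and merging at 100 bp and 500 bp bins give no value for genes or lists. Beside counts of 0, the numbers at an unadjusted p under 0.05 stand with the results, from the same exact tests. Unknown depth limits what absence of a peak can mean.

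Over 20 clones the following changed. With all deposited peaks, there were 0 monocytic-higher regions, 0 progenitor-higher regions, 8 monocytic-higher genes, 8682 progenitor-higher genes, 0 lists higher and 15 lists lower. The similarity within states (progenitor minus monocytic) was -0.0498 (p = 0.0587). Ankrd33b (-1.65), Nr3c1 (-2.1), Sorl1 (-2.3), Amotl2 (-0.3), Actn1 (-1.4), Retreg1 (-1.15), Atrnl1 (-3.45) and Gsr (-1.45) turned direction. Exoc2 (-1), Itpkb (-3.6), Csf1r (-1.25), Spi1 (-1.1), Cebpa (-2.5), Irf8 (-5.3) and Kit (-5.5) turned direction. Monocyte and macrophage identity (-1.46), primary granule (-0.72), mature neutrophil (-0.524), antigen presentation (-1.19), inflammatory response (-1.77), interferon response (-1.01), phagocytosis and lysosome (-1.88) and adhesion and migration (-2.47) turned among the lists. Erythroid and megakaryocyte (-1.23), mast cell (-1.94), cell cycle (-1.08), housekeeping (-1.3) and myeloid transcription factors (-3.06) turned among the lists. With 14000 peaks per list, there were 0 lists lower and 4902 regions shared by partners. Arhgef10l (0.35), Csf1r (-0.15) and Irf8 (-0.25) turned direction. Erythroid and megakaryocyte (-0.0107) and mast cell (-0.075) turned among the lists. With 24 clones at 11500 peaks, there were 448 progenitor-higher regions, 315 monocytic-higher genes, 57 progenitor-higher genes and 4056 regions shared by partners. Arhgef10l (0.458), Ackr3 (0.167), Csf1r (-0.208) and Irf8 (-0.167) turned direction. Dendritic cell (0.0192) and mast cell (-0.104) turned among the lists. With lists that differed by less than 2 times, there were 1404 progenitor-higher regions, 453 monocytic-higher genes, 233 progenitor-higher genes, 4 lists lower and 0 regions shared by partners. The gene-end share difference was 3.45 (p = 0.385) and the similarity within states (progenitor minus monocytic) was -0.0018 (p = 0.951). Erythroid and megakaryocyte (-0.181) and housekeeping (-0.0321) turned among the lists. In 500 bp bins, there were 0 monocytic-higher regions and 0 progenitor-higher regions. Without the pairing by clone as a block, there were 2695 monocytic-higher regions, 1453 progenitor-higher regions and 452 monocytic-higher genes. The log10 difference in list length was -0.185 (p = 0.0369). Within 10 kb of a gene end, there were 488 monocytic-higher genes and 41 progenitor-higher genes. Chl1 (0.05) and Irf8 (-0.15) turned direction. Stem and progenitor (0.0833) and erythroid and megakaryocyte (-0.0429) turned among the lists. With presence per gene, there were 0 monocytic-higher genes, 0 progenitor-higher genes and 5 lists higher. Csf1r (-0.05) turned direction. Stem and progenitor (0.0167), dendritic cell (0.0346), erythroid and megakaryocyte (-0.0286) and mast cell (-0.0875) turned among the lists. With support of 6 libraries, there were 1410 progenitor-higher regions. In clones 1 to 13 alone, there were 2166 monocytic-higher regions, 2155 progenitor-higher regions, 595 progenitor-higher genes, 4 lists lower and 0 regions shared by partners. The gene-end share difference was -0.134 (p = 0.463), the similarity within states (progenitor minus monocytic) was 0.0501 (p = 0.0186) and the log10 difference in list length was -0.0483 (p = 0.011). Kit (-0.0909) turned direction. Erythroid and megakaryocyte (-0.247), cell cycle (-0.0625) and housekeeping (-0.159) turned among the lists. In clones 15 to 26 alone, there were 0 monocytic-higher regions, 0 progenitor-higher regions, 0 monocytic-higher genes, 0 progenitor-higher genes, 0 lists lower and 0 regions shared by partners. The partner similarity (own minus other) was -0.000561 (p = 0.646). Csf1r (-0.333) turned direction. Stem and progenitor (0.349), dendritic cell (0.385), lymphoid (0.0139) and mast cell (-0.185) turned among the lists. Without clones 16 and 20, the similarity within states (progenitor minus monocytic) was -0.0675 (p = 0.056). Erythroid and megakaryocyte (-0.00794) turned among the lists. Without clone 18, there were 676 monocytic-higher regions and 347 progenitor-higher regions.

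Within clones 1 to 13 these results changed under the alternatives tried there. With all deposited peaks, there were 1331 monocytic-higher regions, 372 monocytic-higher genes, 1045 progenitor-higher genes, 1 list higher and 7 lists lower. The gene-end share difference was 2.37 (p = 0.0107). Hoxb8 (-0.0909), Cebpa (-0.182) and Irf8 (-2.45) turned direction. Antigen presentation (-0.214), interferon response (-0.182), adhesion and migration (-0.358), mast cell (-0.348), cell cycle (0.00568) and myeloid transcription factors (-0.364) turned among the lists. With 14000 peaks per list, there were 941 monocytic-higher regions, 913 progenitor-higher regions, 284 monocytic-higher genes, 219 progenitor-higher genes, 2 lists lower and 109 shared regions at an unadjusted p under 0.05. The gene-end share difference was 0.665 (p = 0.0342) and the similarity within states (progenitor minus monocytic) was 0.0102 (p = 0.493). Rcbtb2 (-0.909) and Irf8 (-0.364) turned direction. With clones 3 and 10 at 18000 peaks, there were 1296 monocytic-higher regions, 1076 progenitor-higher regions, 321 monocytic-higher genes and 234 progenitor-higher genes. The gene-end share difference was 0.33 (p = 0.118) and the similarity within states (progenitor minus monocytic) was 0.0278 (p = 0.0703). Irf8 (-0.154) turned direction. In 500 bp bins, there were 1368 progenitor-higher regions. Without the pairing by clone as a block, there were 3800 monocytic-higher regions, 3882 progenitor-higher regions, 1224 monocytic-higher genes and 1042 progenitor-higher genes. Within 10 kb of a gene end, there were 0 monocytic-higher genes and 0 progenitor-higher genes. Irf8 (-0.273) turned direction. Interferon response (-0.049) turned among the lists. With presence per gene, there were 0 monocytic-higher genes, 0 progenitor-higher genes, 2 lists higher and 2 lists lower. Antigen presentation (-0.0195), phagocytosis and lysosome (-0.0455), mast cell (-0.0303) and myeloid transcription factors (-0.00909) turned among the lists.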

Other observations

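Gene families outside the fixed lists were also looked at in clones 1 to 13. The families were chosen after seeing the data, so a test of them on the same clones would not be evidence, and their values are given without one. Tests of the neutrophil gain by its relation to the monocyte gain and by random lists were set before their results were seen, and the regression after, on a set of clones chosen after seeing the data. Guanylate-binding proteins, which act in defence within the cell, had a mean difference of -0.739 ± 0.498 peaks per gene, monocytic minus progenitor (SD, n = 11, lower in 11 of 11), -1.16 with all deposited peaks and -0.636 with 14000. Semaphorins, guidance molecules, had -0.383 ± 0.176 (lower in 11 of 11), and -0.63 and -0.234 in the other settings. Cathepsins, lysosomal proteases, had 0.295 ± 0.285 (higher in 8 of 11), and 0.439 and 0.167.

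Values of the other families are the main value, that with all deposited peaks and that with 14000. Toll-like receptors had 0.655, 0.255 and 0.455, CD300 receptors 0.384, 0.182 and 0.475, and S100 proteins 0.147, 0.154 and 0.308. Paired immunoglobulin-like receptors had 0.582, 0.527 and 0. Ephrin receptors had -0.848, -1.35 and -0.0455, and GIMAP proteins -0.39, -0.597 and -0.039. C-type lectin receptors (0.327, -0.0691 and 0.182), Schlafen proteins (0.5, -0.136 and 0.424) and the Hoxb cluster (0.364, -0.182 and 0.0909) turned with all deposited peaks. The Hoxa cluster had 0, -0.182 and 0, matrix metalloproteinases -0.0584, -0.266 and 0.0325, and sphingosine phosphate receptors -0.409, -0.159 and -0.568.

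A share of neutrophils that differs between clones may lie behind the gain of neutrophil genes and would run against the monocyte gain, but both ran together over 11 clones (Pearson's r = 0.799, permutation p = 0.00335, Spearman's rho = 0.740, p = 0.0118, and r = 0.783, p = 0.0125, without the 2 clones farthest from the median). It cannot be told apart from clones that changed more, since the neutrophil gain was larger where the states of a clone were less alike (r = -0.893 with their Jaccard index, permutation p = 6e-05), and with that regressed out the gains had r = 0.371 (p = 0.261). The list shares 0 of its 17 entries with other lists, monocytes are known to express S100a8, S100a9 and Chil3 as well, and no sort or gate is given in the sources used here. Of 10000 random lists matched on peaks per gene, 0% reached the mean gain of 0.875 over the 16 tested genes of the neutrophil list (highest 0.778). The gain of this list, the largest among the fixed lists, was thus above that of random genes. Whether peaks around genes rose in general cannot be decided by this test. Both states were cut to the same number of peaks, and the random lists had a mean gain of 0.00813. A share of neutrophils that is the same in all clones, or genes that monocytic cells themselves open, stay open and untested.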
